A study of Mus musculus with 4 samples.

How the data were processed

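Colon epithelial cells were collected from 4 groups of C57BL/6 mice, 6 to 8 weeks old, at day 12 of the azoxymethane and dextran sulfate sodium model. Per the labels' protocols, colons were opened, washed, cut and shaken in EDTA, the released cells were pelleted, RNA was extracted with Trizol, and 200 ng of total RNA was labelled for Affymetrix Mouse Gene 1.0 ST arrays. No cell sorting is described, so other cell types released with the epithelium would be measured with it. Each genotype had 1 array: both genes deleted (DKO), Bmi1 deleted (Bmi1_KO), Mel18 deleted (Mel18_KO) and wild type (WT). The labels give the genotypes as Bmi1ΔIEC Mel18ΔIEC, Bmi1ΔIEC, Mel18ΔIEC and WT. Bmi1_KO and Mel18_KO are short names used here.

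The deposited values are probe set intensities on a linear scale, made by the authors with Affymetrix Expression Console and RMA, per the submitters' processing notes. RMA corrects background, normalizes the arrays to one distribution of values by quantiles and summarises the probes of a set, so a difference shared by most genes would be removed before deposit. Software versions and the annotation release are not given in the sources used here. The intensities ran from 4.70 to 13738 over the 4 arrays and 35556 probe sets, and log2 was taken before any difference. Intensities carry no count of molecules, so precision is limited by the number of arrays and, for dim probe sets, by signal over background.

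Probe sets were named from the platform annotation, in which 21797 carried 1 gene symbol, 1613 carried several and 12146 were not listed with a gene. Of those with 1 symbol, 21698 had a gene identifier found in the RefSeq gene table, and 0 symbols needed an update. Probe sets with several symbols were not named. For the 999 genes with more than 1 probe set, the set with the highest mean was used, giving 19946 genes. The 12527 genes with a log2 intensity of at least 6 on the highest of the 4 arrays were analysed. Genome coordinates were not used here.

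Differences between arrays were taken on the log2 scale, and genes at least 2-fold apart were counted in each direction for DKO, Bmi1_KO and Mel18_KO against WT, for DKO against the mean of the 3 other arrays, and for the departure from additivity (DKO minus Bmi1_KO minus Mel18_KO plus WT). With 1 array per genotype these are values with no test. The spread of 1 array was bounded from the 3 orthogonal contrasts of the layout (loss of Bmi1, loss of Mel18 and their interaction, each as a difference of means of 2 arrays), taking the scaled median absolute deviation across genes. It was 0.313, 0.296 and 0.288, and the smallest was used as the error scale of 1 array, or 0.407 for a difference of 2 arrays. True differences enter these contrasts, so this is an upper bound for a typical gene. Average changes with loss of Bmi1 or Mel18 were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment, threshold 0.05) in an additive model with 1 residual degree of freedom. Correlations across genes compared the pairs of arrays that differ in the same gene. For a shared array, 4 simulated unchanged arrays with normal noise at the error scale gave the value at that noise.

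For 50 gene lists of pathways and cell types, the median difference was set among 10000 random lists of the same size, matched on mean expression in 20 bins, and members at least 1.5-fold apart were counted. Intervals in the closing section are 95% bootstrap intervals over genes, which are not independent replicates, except where called exact. A list was said to stand apart at a percentile of 2.5 or less or of 97.5 or more. The percentile describes these arrays and is not a p-value. The genes named were Bmi1 and Pcgf2 first, then the 12 highest and 12 lowest genes at least 2-fold apart in each difference against WT, the 5 highest and 5 lowest in the other comparisons, up to 4 members with the largest differences in each list described, and Reg3b, Reg3g, Cdkn2a, Lgr5, Mki67 and Muc2. Small RNAs, unnamed gene models, olfactory and vomeronasal receptors and antigen receptor segments were left out of this ranking. For average changes both pairs of arrays had to lie on the same side. The grouping of arrays, tests, lists, naming rule and the alternatives below were fixed before the data were examined. Ptprc, and Fabp2 and Fabp6 in the comparison of DKO with WT, fall outside the naming rule and were picked after their values were seen, as were the highest and lowest genes, up to 12 each way, of DKO against the single deletions, the seminal vesicle genes, the gene families by symbol and the comparisons without the WT array.

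Alternatives were no filter on dim genes, a floor of 8, cyclic loess, median centring, log2 of the value plus 32, thresholds of 1.5-fold and 3-fold, the mean of a gene's probe sets, all probe sets, list means, unmatched random lists, and a trend in eBayes. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The procedures were tested on simulated data, made of the mean of each of the 12527 genes plus normal noise at the error scale, with known changes added on DKO. The 2-fold rule recovered 91.0% of genes changed by 1.5 and 100% of genes changed by 3 on the log2 scale and took up 1.26% of unchanged genes. With changes added on DKO and Bmi1_KO alike, the additive fit for loss of Bmi1 recovered 93% of 100 genes changed by 1.5 and 100% of 100 genes changed by 3, with 3 false calls. That simulation gave every gene the same noise and no departure from additivity, unlike these arrays, so its recovery does not carry over to them. All 20 lists of 30 genes shifted by 0.5 stood apart, and 12 of 200 unshifted lists did, with simulated genes that were independent of each other.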

Results

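Gene expression was measured in epithelial cells released with EDTA from the colons of C57BL/6 mice at day 12 of a colitis-associated cancer model. In this model a single injection of azoxymethane (10 mg/kg), a colon carcinogen, is followed by 5 days of dextran sulfate sodium (3.5% in drinking water), which injures the colonic lining. The 4 samples form a 2 by 2 layout of epithelial deletions of Bmi1 and of Mel18 (gene symbol Pcgf2), which encode related subunits of Polycomb repressive complex 1, a chromatin repressor. There was 1 array each for the mice lacking both genes (DKO), for each single deletion (Bmi1_KO and Mel18_KO) and for wild type (WT). The comparisons ask which transcripts differed with each deletion, and which differed on the array lacking both genes beyond what each deletion showed alone. Median intensity was 72.96 on DKO, 72.91 on Bmi1_KO, 67.04 on Mel18_KO and 69.22 on WT over 35556 probe sets. With no replicate of any genotype, no difference between a pair of arrays has a replicate check, and the number of arrays limits the precision. The error scale of a difference between 2 arrays was at most 0.407 on the log2 scale for a typical gene, from the contrasts among the 4 arrays, and at most 0.191 from the closest pair of arrays, Bmi1_KO and WT, a bound chosen after the data were seen.

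The deleted genes were examined first. Bmi1 (probe set 10469514) had a log2 intensity of 7.64 on DKO, 7.43 on Bmi1_KO, 6.999 on Mel18_KO and 7.25 on WT, so it was not lower on the arrays whose labels state its deletion. Pcgf2 (probe set 10390458) read 6.81 on DKO, 6.72 on Bmi1_KO, 6.84 on Mel18_KO and 6.96 on WT, and its differences from WT were -0.15, -0.24 and -0.13. Which exons were deleted is not given in the sources used here, and a probe set summarised over a whole transcript also reads RNA outside a deleted part, so neither gene checks the labels. The arrays are therefore named by the genotypes that their labels state, and every direction below rests on those labels.

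The array labelled DKO stood apart from the others. Its Pearson correlation with the other arrays across 12527 genes was 0.906 with Bmi1_KO, 0.885 with WT and 0.878 with Mel18_KO, whereas the other pairs of arrays lay between 0.978 and 0.982. On DKO, 629 genes were at least 2-fold higher than on each other array and 591 were at least 2-fold lower. The same count gave 3 and 4 genes on Bmi1_KO, 0 and 70 on Mel18_KO, and 16 and 4 on WT. Among the genes highest on WT were secretory proteins of the seminal vesicle: Svs4 read 12.17 on WT against 4.16 on DKO, 5.73 on Bmi1_KO and 4.67 on Mel18_KO. The 12 genes of a seminal vesicle list, written after these values were seen, had a median log2 intensity of 9.60 on WT, 4.17 on DKO, 4.45 on Bmi1_KO and 4.02 on Mel18_KO. All 12 were therefore among the genes 2-fold lower in each comparison against WT.

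**Figure D1:**
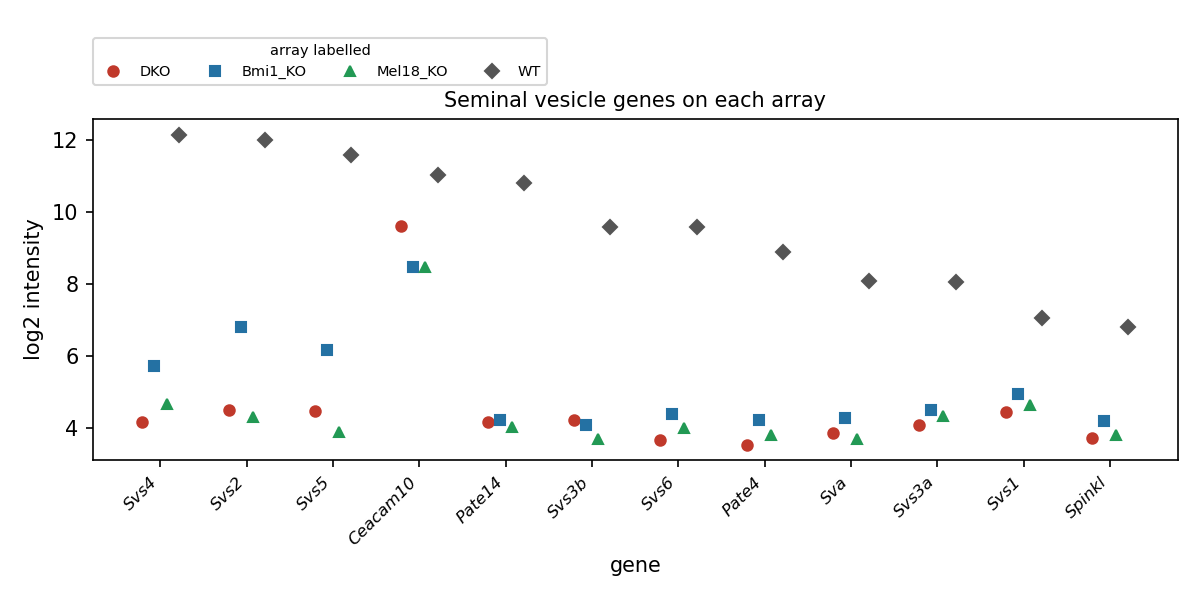
Log2 intensity (vertical axis) of the 12 seminal vesicle genes (horizontal axis, ordered by their level on WT) on each of the 4 arrays, 1 point per array. Each gene is highest on WT, from 12.17 for Svs4 to 6.81 for Spinkl, and Svs2, Svs5 and Svs4 lie higher on Bmi1_KO (6.82, 6.18 and 5.73) than on DKO and Mel18_KO.

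Against WT, the highest genes on the array labelled DKO included antimicrobial lectins and enterocyte peptidases, and the lowest, seminal vesicle genes aside, included a fatty acid desaturase and a cytochrome. Reg3b (probe set 10539179) and Reg3g (probe set 10545569), secreted lectins that act on gut bacteria, were 86.9-fold and 61.8-fold higher, with log2 differences of 6.44 and 5.95. Apoa1, the main protein of high-density lipoprotein, was 43.3-fold higher (5.44), followed by the peptidases Naaladl1 (4.36) and Enpep (4.18), the pantetheinase Vnn1 (3.97), Ly6i (3.80), Ly6d (3.71), Tm4sf5 (3.70), the chaperone clusterin, Clu (3.69), Gml (3.52) and the myeloid lectin receptor Clec4n (3.51). Of the 12 lowest genes 9 were on the seminal vesicle list, among them Svs4 (-8.01), Svs2 (-7.51) and Svs5 (-7.11). Most of them read under 6 on the deletion arrays, where the signal is near background, so differences of this kind are rough and their order carries no weight. The others were the fatty acid desaturase Scd1 (-4.22, 18.6-fold), the colonic cytochrome Cyp2c55 (-3.57) and the sialyltransferase St8sia5 (-3.17). Lgr5, a crypt stem cell receptor, and Mki67, a proliferation marker, gave -1.49 and -1.45, while the goblet cell mucin Muc2 and the cell cycle inhibitor Cdkn2a gave 0.22 and 0.44. In all, 918 genes were at least 2-fold higher and 1026 at least 2-fold lower on DKO than on WT, where normal noise at the error scale would give 175. Centring each array on its median turned that split to 1110 higher and 719 lower.

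**Figure D2:**
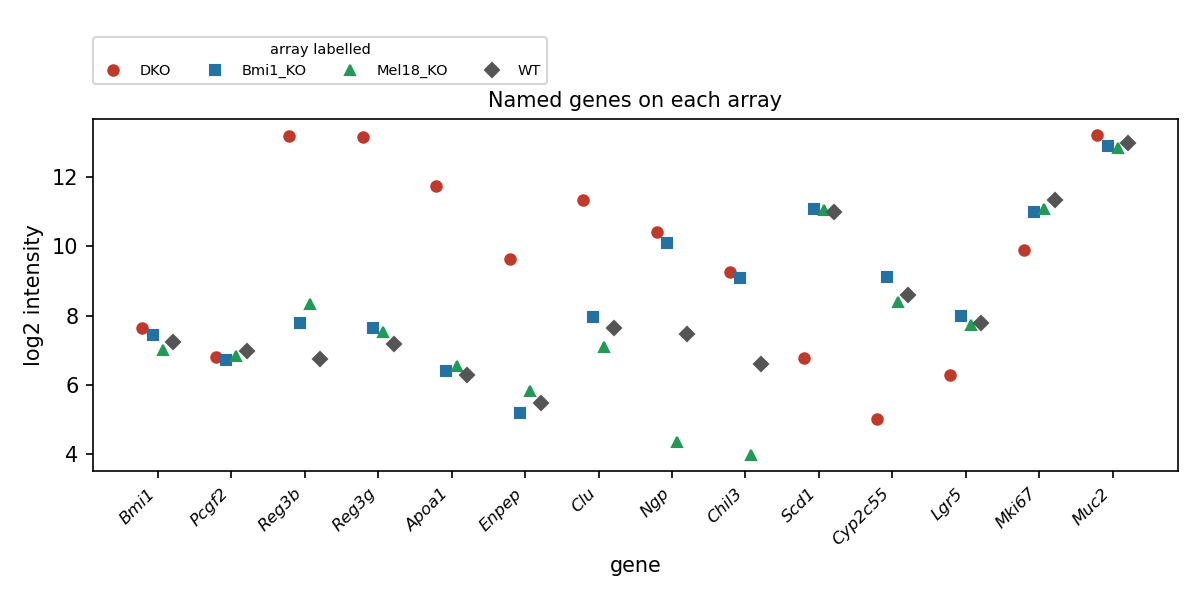
Log2 intensity (vertical axis) of 14 named genes (horizontal axis) on each of the 4 arrays, 1 point per array. Reg3b and Reg3g lie at 13.18 and 13.14 on DKO and at no more than 8.32 elsewhere, Scd1 lies at 6.76 on DKO and at no less than 10.98 elsewhere, and Ngp runs from 4.35 on Mel18_KO to 10.41 on DKO.

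Genes of cell division were lower on DKO almost without exception. Among 42 measured DNA replication genes 41 were at least 1.5-fold lower than on WT and 0 higher, with a median of -1.41 and examples in Gins1 (-2.03) and Mcm5 (-1.85). Among 65 mitosis genes 63 were lower and 0 higher, with a median of -1.45, including Racgap1 (-2.27), Pbk (-2.10) and Plk1 (-1.99). Nucleolar and MYC target genes followed, with 37 of 39 lower and a median of -1.32 (Srm -1.92, Grwd1 -1.83), and so did 20 of 32 DNA repair genes (median -0.79, Apex1 -1.75). Of 20 crypt base stem cell genes 11 were lower, among them Ascl2 (-1.95), Myb (-1.94), Lrig1 (-1.91) and Cdca7 (-1.83), while 3 were higher. Each of these 5 lists had a median below all 10000 random lists matched on expression, which describes these arrays and is no p-value.

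Several metabolic lists differed, while fatty acid oxidation and ketogenesis genes did not stand apart (median -0.12, 5 of 32 higher and 3 lower). Sterol and fatty acid synthesis genes had a median of -0.84, with 17 of 29 lower, led by Scd1, Fads1 (-2.12), Scd2 (-1.76) and Fasn (-1.46). Respiratory chain genes were lower in 20 of 41 cases and higher in 0 (median -0.57, Cyc1 -1.18). Of 45 detoxification enzymes 22 were lower and 7 higher (median -0.56), including Gstm1 (-2.73), Gstm3 (-2.69) and Gsta3 (-2.53). Against the single deletions this list's median was -0.19 and it no longer stood apart, although 21 were still lower and 10 higher. Glycolysis and hypoxia genes went the other way, with 13 of 33 higher and a median of 0.50, among them Adm (2.06), Pfkfb3 (1.91) and Bnip3 (1.80).

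Transcripts of white blood cells and of inflammation were higher on DKO. In the neutrophil list 26 of 30 genes were at least 1.5-fold higher than on WT and 0 lower, with a median of 2.25 (Hcar2 3.00, Ngp 2.93, Clec4d 2.73). Mononuclear phagocyte genes were higher in 30 of 34 cases (median 1.96, Ms4a6c 2.48, Cybb 2.45), and the pan-leukocyte gene Ptprc was higher by 2.34. Cytokine and NF-kB genes were higher in 47 of 53 cases (median 1.44), including Ifng (3.08), Il6 (2.96) and Il1a (2.89), although 6 of these 53 genes also stand on lists of other cell types. Interferon-induced genes had a median of 0.55, with 22 of 49 higher (Gbp4 3.29, Gbp5 2.44), and 9 of 9 MHC class II genes were higher (median 1.19). Stromal transcripts were higher as well: 18 of 22 endothelial genes (median 0.93, Cd93 2.14) and 21 of 31 fibroblast genes (median 0.76, Pdpn 1.82). Lymphocyte lists differed less, with medians of 0.45 for T and NK cells and 0.36 for B and plasma cells.

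Common epithelial genes were level, while lists of regional, repair, goblet cell and tuft cell genes differed in this unsorted isolate. The pan-epithelial list had a median of 0.11, with 4 of 32 genes higher and 6 lower, among them the homeobox gene Cdx1 (-1.36). Small bowel genes were higher in 16 of 22 cases (median 1.29), led by Apoa1, Enpep, the intestinal alkaline phosphatase Alpi (3.50) and the lipoprotein assembly factor Mttp. The ileal bile acid-binding protein Fabp6 gave -1.16, but it read 4.77 on DKO and 5.93 on WT, near background, so this difference is rough. The bile acid transporter Slc10a2 was higher by 3.05. Repair and fetal-like epithelial genes had a median of 0.50, with 19 of 40 higher, including Ly6d, Clu and Il33 (2.66), and 5 lower, including the basal keratin Krt5 (-2.95). Of its genes 5 also stand on lists of other cell types, as do 6 of the antimicrobial and injury list, next to the higher myeloid and stromal genes. The antimicrobial and injury list had a median of 0.65, with 19 of 38 higher and 7 lower. Mature colonocyte genes had a median of 0.05, with 14 of 48 lower, among them the magnesium channel Trpm6 (-2.33), and 7 higher. Goblet cell genes stood apart with a median of 0.32, 8 of 30 higher and 5 lower. Tuft cell genes did so with a median of 0.71, 8 of 14 higher and 0 lower, and 2 of them also stand on lists of other cell types.

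Polycomb subunits and developmental regulators differed little as groups, unlike cell cycle inhibitors. Subunits of Polycomb repressive complexes 1 and 2 had medians of -0.17 and -0.14, with 4 of 21 and 1 of 12 genes lower and 0 higher, and L3mbtl2 (-1.49) and Pcgf6 (-1.22) differed furthest. Developmental regulators, transcription factor genes that Polycomb holds silent in many tissues, had a median of 0.04 over 33 measured genes. Of these 7 were higher, including Gata4 (2.89) and Gata3 (2.57), and 0 were lower. Among the 33 genes 1 also stands on a list of other cell types. Pax3 (1.495), Sox2 (1.21) and Zic2 (6.02 on DKO, 5.07 on WT) passed the floor of 6 on DKO alone, so the filter itself favours higher calls among such dim genes. Hox genes had a median of -0.30, with 6 of 20 lower and 0 higher (Hoxd13 -1.72). Their median was -0.34 both against the single deletions and against all 3 other arrays, where the list stood apart (percentiles 0.81 and 1.13). Cell cycle inhibitors had a median of 0.71, with 8 of 15 higher, among them Btg2 (1.26), a list that stood apart, while Cdkn2c was lower (-1.64). Across all 50 lists, 30 stood outside the central 95 percent of random lists in this comparison. Lists of independently drawn genes would give 2.5, but members of a list need not vary independently, so 2.5 is not a true chance rate. On Bmi1_KO 29 lists stood outside and on Mel18_KO 27, so this number is not particular to DKO.

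**Figure D3:**
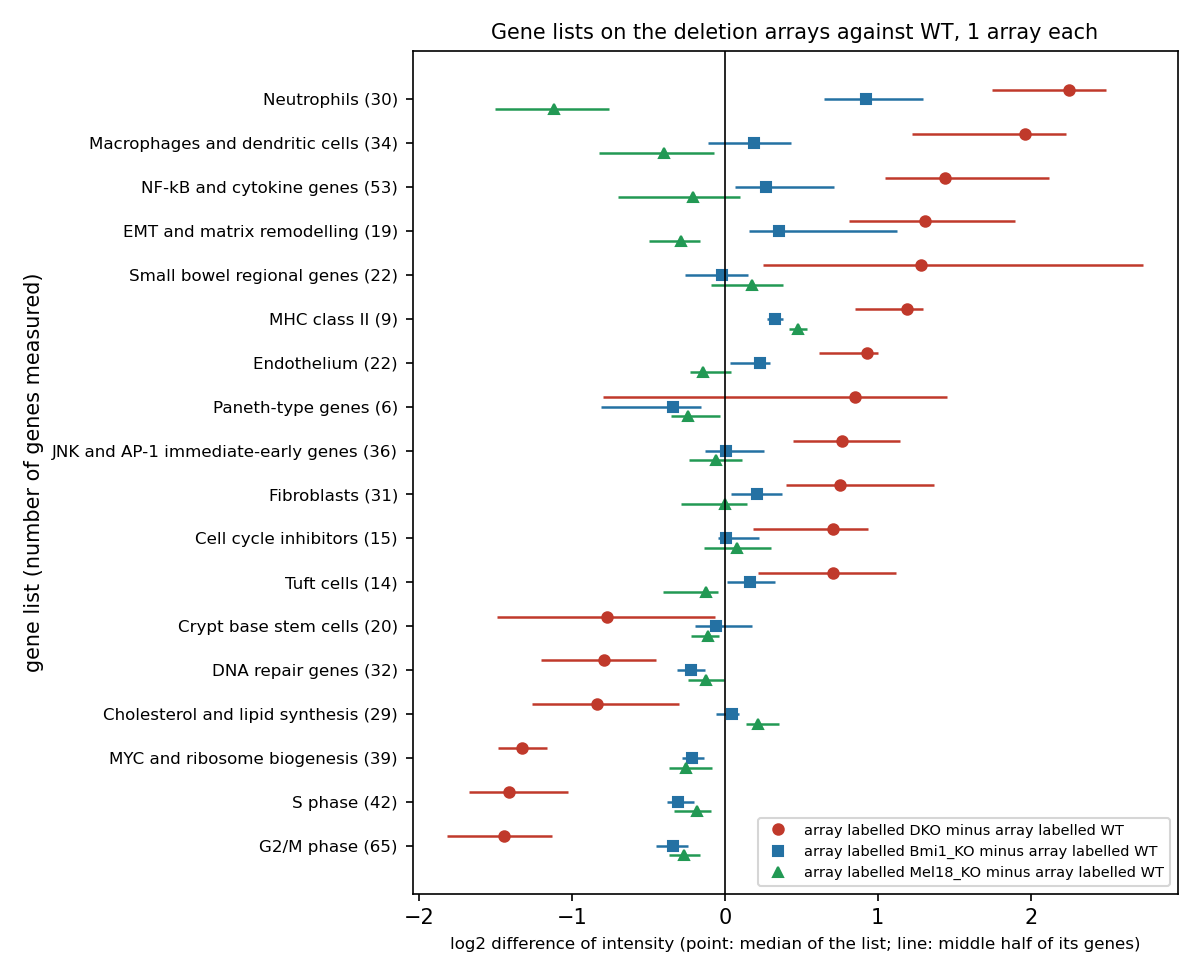
Median log2 difference from WT (horizontal axis, points) for the gene lists of at least 5 measured genes that lay furthest from 0 on DKO, with lines for the interquartile range of each list's genes. Neutrophil genes lie at 2.25 on DKO, 0.92 on Bmi1_KO and -1.12 on Mel18_KO, and mitosis genes at -1.45, -0.34 and -0.26.

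Because the WT array carried seminal vesicle transcripts, DKO was also set against the mean of Bmi1_KO and Mel18_KO, a comparison chosen after the data were seen. Reg3g (5.56), Apoa1 (5.25), Reg3b (5.13), Ly6i (4.44) and Naaladl1 (4.26) were again the highest genes. The lowest were Scd1 (-4.29), Cyp2c55 (-3.73), the carbonyl reductase Cbr2 (-3.43), the peroxisomal oxidase Hao2 (-3.02) and the glutathione transferase Gstm1 (-2.68), followed by Cyp2c68, Gstm3, Slc37a2, Trpm6, Acer1, Kcnn4 and Cyp2f2. Of the 918 genes 2-fold higher and 1026 lower against WT, 799 and 697 were also 2-fold apart in the same direction here. Both differences contain the DKO array, which raises this overlap and the likeness of list medians by construction. Several lists kept medians of similar size, at -1.16 for DNA replication, -1.13 for mitosis, 2.25 for neutrophils, 2.05 for mononuclear phagocytes and 1.39 for small bowel genes. Others did not: detoxification enzymes went from -0.56 to -0.19 and squamous epithelial genes from -0.62 to -0.05, and neither list stood apart without the WT array. By count, 21 of 45 detoxification enzymes were still at least 1.5-fold lower and 10 higher, against 22 and 7 relative to WT. For 14 squamous genes these counts were 4 and 2, against 7 and 2. Cell cycle inhibitors were higher in 4 of 15 cases in place of 8, with a median of 0.48.

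Against the mean of all 3 other arrays, Reg3g (5.69), Reg3b (5.56), Apoa1 (5.32), Naaladl1 (4.30) and Ly6i (4.23) were highest on DKO, and Scd1 (-4.27), Cyp2c55 (-3.68), Svs4 (-3.36), Cbr2 (-3.28) and Svs2 (-3.22) lowest. There were 911 genes at least 2-fold higher and 866 lower. The split became 1048 and 612 after cyclic loess and 1094 and 587 after median centring, so the balance between higher and lower genes depended on the scaling. Neutrophil (median 2.19), mononuclear phagocyte (2.02) and small bowel genes (1.36) stood highest among the lists, and mitosis (-1.25), DNA replication (-1.19) and MYC target genes (-1.16) lowest.

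The departure from additivity, DKO minus both single deletions plus WT, asks whether the array lacking both genes differed by more than the 2 single differences together. It was at least 2-fold for 1026 genes above additivity and 805 below it. Among the highest were the seminal vesicle genes Pate14 (6.69), Svs3b (6.05), Svs5 (6.00), Svs4 (5.93) and Svs2 (5.38), which are low on all 3 deletion arrays and so depart from additivity through the WT array. The lowest were Scd1 (-4.37), Cyp2c55 (-3.90), Cbr2 (-3.87), Fabp6 (-3.44) and Hao2 (-3.36). Fabp6 read 4.77 on DKO and 5.93 on WT, near background, so its value is rough. Of the genes 2-fold higher on DKO than on WT, 714 were also 2-fold above additivity, and of the lower ones 482 were also below it. The DKO and WT arrays enter both values, so these overlaps are no independent check. After cyclic loess the split was 1203 and 521, and after median centring 1189 and 584. This value uses all 4 arrays once and has no separate estimate of its error. The noise of all 4 arrays enters it, so it is noisier than a difference of 2 arrays. Its scaled median absolute deviation across genes was 0.576. The error scale was taken from this same contrast, so these counts cannot be judged against it.

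The array labelled Bmi1_KO had higher neutrophil, cytokine and matrix-remodelling transcripts than WT and lower interferon-induced ones. The highest genes were the neutrophil granule protein Ngp (2.62, 6.13-fold), the chitinase-like protein Chil3 (2.47), the matrix proteases Mmp3 (2.46), Mmp13 (1.85) and Mmp10 (1.72), the decoy receptor Il1r2 (2.41), the chemokines Cxcl3 (1.82) and Cxcl2 (1.64), Sprr2f (1.78), Alox5ap (1.66), Tlr13 (1.63) and Stfa2 (1.56). Of these, Mmp3, Sprr2f and Stfa2 read under 6 on WT, near background, so their differences and rank are rough. Of the 12 lowest genes 11 were on the seminal vesicle list, and the other was St8sia5 (-2.83). Reg3b was higher by 1.04 and Reg3g by 0.44, while Cdkn2a (0.32), Lgr5 (0.20), Muc2 (-0.10) and Mki67 (-0.35) differed by less. In the neutrophil list 24 of 30 genes were at least 1.5-fold higher and 1 lower (median 0.92), against 7 of 34 mononuclear phagocyte genes (median 0.19), 17 of 53 cytokine and NF-kB genes (median 0.27) and 9 of 19 matrix-remodelling genes (median 0.36), a list with 4 members that also stand on lists of other cell types. Fibroblast (median 0.21) and endothelial genes (0.23) stood apart beside them. The endothelial direction depended on the filter: with a floor of 8 that list passed to the other side of the random lists' middle. Interferon-induced genes had a median of -0.44, with 20 of 49 lower, including Rsad2 (-1.26), Ifit2 (-1.18) and Ifit1 (-1.14), although the interferon-inducible GTPase Iigp1 was higher (1.22). This list was also low on Mel18_KO against WT (-0.19, 6 of 49 lower), and Bmi1_KO lay below Mel18_KO by a median of 0.18. Enteroendocrine genes had a median of -0.32 with 5 of 25 lower, led by the neuropeptide gene Tac1 (-2.04), and were also low on Mel18_KO (-0.18). The heat shock gene Hspa1a gave -2.33. Mitosis genes (median -0.34) and DNA replication genes (-0.30) were lower by small amounts, with 4 of 65 and 2 of 42 past 1.5-fold. There were 69 genes at least 2-fold higher and 45 lower (292 and 73 over all probe sets). Normal noise at the error scale, an upper bound, would give 175 genes, more than the 114 found here and the 120 on Mel18_KO. The spread across genes was only 0.191 for Bmi1_KO and 0.217 for Mel18_KO against WT, narrower than the error scale of 0.407. The 175 is therefore too large an expectation for these differences. Normal noise at the bound from the closest pair, which is Bmi1_KO and WT itself, would give 0. Noise need not be normal or alike in every gene, and there are no replicates. How many of these genes lie beyond noise therefore cannot be said.

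The array labelled Mel18_KO had lower neutrophil and inflammatory transcripts than WT. Of 30 neutrophil genes 23 were at least 1.5-fold lower and 0 higher (median -1.12), including Retnlg (-2.15) and the dim Ngp (-3.13), Mmp8 (-2.69) and Chil3 (-2.63), which read under 6 on Mel18_KO, and 10 of 34 mononuclear phagocyte genes were lower (median -0.40). Cytokine genes were lower in 14 of 53 cases (median -0.20), including Ccl3 (-2.22), Ptgs2 (-1.87) and Il1a (-1.69), and so were the acute-phase genes Saa3 (-2.70) and Lcn2 (-2.20). Squamous keratins were lower too, with 5 of 14 genes of their list and a median of -0.35 (Krt5 -2.40, Krt17 -1.89, Krt6a -1.83). The same list was also low against WT on DKO (-0.62) and Bmi1_KO (-0.19), so it was highest on the WT array. The highest genes were Srsy (1.74), Reg3b (1.59, 3.01-fold), Fabp6 (1.42), the B cell receptor component Cd79a (1.35), Alpi (1.19), Iigp1 (1.12), H2-Ob (1.12), Tmem139 (1.11), Pla2g4f (1.04) and the guanylin gene Guca2a (1.02). Of these, Srsy, Fabp6, Cd79a and H2-Ob read under 6 on WT, near background, so their differences and rank are rough. Differences were small for Reg3g (0.32), Cdkn2a (0.21), Lgr5 (-0.05), Muc2 (-0.15) and Mki67 (-0.28). B and plasma cell genes (median 0.37, 4 of 15 higher), MHC class II genes (0.48), sterol synthesis genes (0.22) and respiratory chain genes (0.18) stood above all or nearly all random lists, by small amounts. MHC class II (0.33), sterol synthesis (0.05) and respiratory chain genes (0.07) also stood apart on Bmi1_KO. The MHC class II list was higher on DKO too (1.19), so it was lowest on WT. Mitosis (-0.26), DNA replication (-0.18) and MYC target genes (-0.25) stood below all random lists on Mel18_KO, by small amounts. There were 18 genes at least 2-fold higher and 102 lower, of which 12 were seminal vesicle genes, while all probe sets, named or not, gave a near-balanced 206 and 250. Without the genes of the seminal vesicle list and of other cell types, a set chosen after the data were seen, 15 and 58 remained.

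Setting the single deletions against each other, also chosen after the data were seen, leaves out the WT array. Bmi1_KO then had 192 genes at least 2-fold higher and 28 lower than Mel18_KO. Of 30 neutrophil genes 24 were at least 1.5-fold higher on Bmi1_KO (median 2.17), with 17 of 34 mononuclear phagocyte genes (median 0.61) and 11 of 19 matrix-remodelling genes (median 0.84).

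The average change with loss of each gene was taken over both pairs of arrays that differ in it. With loss of Bmi1 the highest averages were neutrophil and cytokine genes, Ngp (4.34), Chil3 (3.88), Mmp8 (3.33), Il1r2 (3.10) and Il1a (3.06). Ngp was higher by 2.62 on Bmi1_KO against WT and by 6.06 on DKO against Mel18_KO, where it read 4.35, near background, as did Chil3 (3.97), so the sizes of these differences are rough. The lowest were St8sia5 (-2.59) and the seminal vesicle genes Svs4, Svs6, Pate4 and Svs3a. With loss of Mel18 the highest averages were Reg3b (3.50), Reg3g (2.91), Apoa1 (2.80), Naaladl1 (2.42) and Enpep (2.40), each carried mainly by the pair of DKO and Bmi1_KO, where Reg3b differed by 5.41 against 1.59 for Mel18_KO and WT. The 5 lowest, from Svs2 (-5.01) to Svs6 (-3.16), were seminal vesicle genes. The additive limma fit called 0 genes for either deletion after Benjamini-Hochberg adjustment, with smallest adjusted p-values of 0.849 for Bmi1 and 0.952 for Mel18, and 324 and 138 genes had an unadjusted p under 0.05. Its residual is the departure from additivity itself, with 1 degree of freedom, so the genes that depart most raise the error against which the averages are tested. The 0 calls therefore do not show that average changes are absent.

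The effect of losing a gene was compared between its pairs of arrays, which share no array. Across genes, which are not independent replicates, the differences for Bmi1 had a Pearson r of 0.26 (Spearman rho 0.19) and those for Mel18 an r of -0.06 (rho -0.01). For Bmi1, 54 genes were 2-fold higher in both pairs, where independent sets would share 5.32, and 6 were lower in both against 3.29. For Mel18, 8 genes were higher in both against 1.2, and 7 lower against 6.18. Differences that share the WT array correlated at 0.44 for DKO and Bmi1_KO, 0.11 for DKO and Mel18_KO and 0.41 for Bmi1_KO and Mel18_KO, while simulated unchanged arrays gave 0.49, 0.50 and 0.50 through the shared array alone. The covariances were 0.102, 0.0269 and 0.0406 against simulated values of 0.0812, 0.0817 and 0.0834. The simulated noise was the error scale of 0.288 per array, an upper bound for a typical gene, where the closest pair of arrays gave 0.135. The simulated covariances are therefore likely too large. The first observed value lay above its simulated one, and the others cannot be judged against theirs. The genes 2-fold higher in both numbered 57, 11 and 6, against 5.06, 1.32 and 0.10 for independent sets, and those 2-fold lower in both 24, 22 and 19, against 3.69, 8.35 and 0.37. A shared array raises such overlaps by construction, and 12 of the genes lower in both are the seminal vesicle genes.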

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

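Every test of the seminal vesicle pattern was chosen only after the pattern was seen. Genes of seminal vesicle secretion such as Svs4, Svs2 and Svs5 were highest on WT, with a list median of 9.60 against 4.17, 4.45 and 4.02 on DKO, Bmi1_KO and Mel18_KO, although the member Ceacam10 was well above background on every array (9.64, 8.49 and 8.49 against 11.03). If material of that gland entered the WT sample, a smaller trace on Bmi1_KO should follow the genes' excess on WT. With no array subtracted on both sides, the Spearman rho was 0.55 (bootstrap interval -0.09 to 0.92) and 0.71 (0.171 to 0.935) in the pairings of references, while prostate and epididymis genes were level (-0.005). Seminal vesicle material in the WT sample and a lowering of these genes by loss of Bmi1 or Mel18 cannot be told apart by these tests. A partial lowering on Bmi1_KO could also leave a trace that follows the level on WT, so rho would not separate them at any width. In addition, 12 genes picked for the pattern leave rho wide, and there is 1 wild-type array.

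For the myeloid pattern the test of normalization was planned before the data were examined, and the other tests were chosen only after the result was seen. Neutrophil and mononuclear phagocyte genes were higher on DKO than on WT in 86.7% and 88.2% of members, which is in line with more of these cells in the isolate, with Ptprc higher by 2.34. A lower epithelial share alone should raise every other cell type alike, yet among genes with a mean log2 of at least 7 the median of 51 myeloid genes exceeded that of 37 lymphoid and stromal genes by 1.30 (bootstrap interval over genes 0.905 to 1.608). The gap was 1.44 (1.190 to 1.679) over all 169 measured genes and 1.27 (0.839 to 1.631) with that level taken on Bmi1_KO and Mel18_KO alone, which speaks against this explanation by itself. Cyclic loess left the neutrophil median at 2.34, so this further scaling did not remove the difference. The deposited values were already normalized by quantiles, and loess moved the median of all genes by only 0.07 between DKO and WT. The test therefore cannot exclude an effect of the original normalization. For loss of Mel18 the same neutrophil list had a median of -1.12 with Bmi1 intact and 1.08 with Bmi1 deleted. The difference between these was not tested.

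All tests of the small bowel pattern were chosen only after the result was seen. Small bowel epithelium in the isolate should raise nearly all of its genes. Of the fixed list 72.7% (16 of 22, exact interval 49.8 to 89.3) were at least 1.5-fold higher on DKO. Apoa1, Enpep and Alpi were high, whereas Fabp2 (0.13) and Fabp6 (-1.16) were not. Fabp6 read 4.77 on DKO and 5.93 on WT, near background, so its difference is rough. A more proximal stretch of colon should lower posterior Hox genes more than other Hox genes, and their medians against the single deletions were -0.43 and -0.03, a difference of -0.40 (interval -0.893 to 0.119). A general release of silenced developmental regulators should place that list at the top of random lists, and it stood at percentile 78.8 with dim members kept. These explanations cannot be told apart, because the intervals are wide, the regulator list is mostly dim, and no array comes from small bowel or a known stretch of colon.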

How the results depend on the processing

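The main counts, the additive fits, the error scale, the correlations between pairs, the named genes and the lists (for the differences against WT and DKO against the others) were repeated under the alternatives that apply to them, and a count was taken as moved when it differed by more than 1.5 times. Of 1842 list alternatives 1724 were the same, 46 stronger, 65 weaker and 7 reversed. Of 620 alternatives for named genes 546 were the same and 74 moved. With 32 added before log2, which shrinks differences of dim genes, 74 of 155 named differences moved and 81 were the same. Under cyclic loess, median centring and the mean of a gene's probe sets 0 moved. Of 75 alternatives for the main results 56 were the same and 19 moved. No paired analysis was possible because each genotype has 1 array, and leaving out a replicate could not be run. Counts that stayed within 1.5 times ranged from 1432 to 2752 for DKO against WT, 80 to 119 for Bmi1_KO, 98 to 123 for Mel18_KO, 1302 to 2403 for DKO against the others and 1333 to 1895 for the departure from additivity. The additive fits stayed at 0 genes, the error scale was 0.306 on genes with a mean of at least 8, and the correlations between pairs stayed at 0.25 for Bmi1 and at -0.07 and -0.05 for Mel18. A threshold of 1.5-fold gave 4318 genes for DKO against WT, 445 for Bmi1_KO, 443 for Mel18_KO, 4151 for DKO against the others and 4318 for the departure from additivity, and 3-fold gave 630, 31, 42, 556 and 599, as a lower or higher threshold must. Adding 32 before log2 gave 73 genes for Bmi1_KO and 70 for Mel18_KO. All probe sets, which bring in unnamed ones, gave 365, 456 and, for the departure from additivity, 2872. Alternatives chosen after the data were seen gave 220 genes between Bmi1_KO and Mel18_KO without the WT array, 73 for Mel18_KO without genes of other cell types, and an error scale of 0.135 from the closest pair of arrays. The reversed lists (those passing to the other side of the random lists' middle) were, with a floor of 8, Notch (-0.06), smooth muscle (-0.03), endothelium (-0.11) and circadian genes (-0.15) on Bmi1_KO, T and NK cell genes (-0.61) and mast cell and eosinophil genes (0.49) on Mel18_KO, and without a filter mast cell and eosinophil genes (0.06) on Mel18_KO. These floors change which members are kept, and the cause was not tested further.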

Other observations

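Genes that share a symbol stem were compared as families after the data were seen, for DKO against the mean of the single deletions. Mitochondrial ribosomal proteins were lower, with medians of -0.82 for 48 Mrpl and -0.89 for 29 Mrps genes (Mrps28 -1.64, Mrpl38 -1.62), and so were 13 Timm genes of mitochondrial protein import (-0.97, Timm50 -1.27), 19 nucleoporin genes (-0.84) and the 10 Mcm genes (-1.25). Cytosolic ribosomal proteins were lower by less, at -0.57 for Rpl and -0.49 for Rps, and cyclic loess brought these to -0.39 and -0.28. Higher families were 15 C-type lectins (2.74, Clec4n 3.70, Clec2e 3.34), 10 Ifi genes (1.94, Ifi205 3.50), 11 Cxcl chemokines (1.69, Cxcl9 2.85), 8 Slfn genes (1.498, Slfn1 2.63), 9 carboxylesterases (1.30, Ces3b 1.98, Ces2f 1.82), 13 matrix proteases (1.09) and 9 Bmp genes (0.92, Bmp3 2.48). Against WT the Ifi, Slfn and carboxylesterase medians were smaller, at 1.199, 0.754 and 0.886, the matrix protease median was larger, at 1.725, and all these families were higher on the array where neutrophil (2.25) and mononuclear phagocyte (2.05) lists were higher too. Of 196 families of at least 8 genes 64 stood apart, where lists of independently drawn genes would give 9.8. Genes of a family need not vary independently, so 9.8 is not a true chance rate for families.

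St8sia5, a sialyltransferase, read 6.41 on DKO and 6.76 on Bmi1_KO but 8.77 on Mel18_KO and 9.58 on WT, so it was low on both arrays labelled as lacking Bmi1. Hoxd13 read 7.70 on DKO against 9.11, 9.46 and 9.42 on the other arrays. The Y-linked gene Eif2s3y was high on all arrays (9.43, 8.90, 8.46 and 8.67) and Xist low (3.94, 3.87, 3.87 and 3.78), as in male tissue.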
